A study of Homo sapiens with 5 samples.

How the data were processed

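Gene expression was measured by RNA sequencing in 5 libraries of non-disease human heart right ventricle, the chamber that pumps blood to the lungs. Tissue was frozen, total RNA was taken up in Trizol and libraries were built with a TruSeq RNA kit, per the labels' protocols. The labels gave 1 group only and no second condition, so levels and their spread were described and no groups were compared. Libraries were named library 1 to library 5 after the number in each sample's title. Nothing in the labels said that the 5 samples came from separate donors, so every p-value and SD measures only the spread between these samples, which may be technical.

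The deposited table held normalized read counts, a signal that the authors made by dividing each gene's count by a size factor per library with DESeq2, per the file headers and the submitters' processing notes. The notes also named TopHat2 version 2.1.1, Cufflinks version 2.2.1 and the genome build hg19, with no role or order. The gene annotation, the counting tool, its strand setting and any filter were not given in the sources used here. The table had 25369 entries with gene symbols and no coordinates, and no coordinates are printed here. Of these, 28 symbols had been turned into dates, as spreadsheet programs do, and held 0.132% of the summed values. They were kept in totals and not named as genes.

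Each library's deposited signal values were whole multiples of 1 step, which was worth between 0.701 and 0.8179 normalized counts per read. Dividing by the step gave whole reads for 100% of values, within a tolerance of 0.1 reads, and totals of 80836646 to 88055028 assigned reads per library. These totals cover reads assigned to listed genes. With 3 reads as the limit that a count of 0 allows, a gene listed at 0 could hold a value of up to 2.1 to 2.45, depending on the library, and this limit covers counting error only. The size factors implied by the steps lay between 1.22 and 1.43. Size factors computed from these 5 libraries alone were smaller by a nearly constant ratio of 1.32 to 1.33, so a common scale factor separates the 2 sets and comparisons between libraries are hardly affected by it.

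Libraries were checked against each other for duplicates. A chi-square statistic on the recovered reads lay between 80.1 and 456.9 per gene over all pairs of libraries, so no pair agreed within sampling noise. Spearman's correlation across measured genes, which are not independent replicates, lay between 0.962 and 0.987 for pairs of libraries.

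A gene was called measured at a mean normalized count of at least 10. Gene lists (21 functional lists and 19 cell type lists), 24 gene pairs, the tests of pairs and of list spread and the rule for named genes were fixed before the data were examined. Named genes were the 10 with the highest mean, the 10 with the largest SD of log2(value + 1) among genes with a mean of at least 100, both genes of each pair and up to 4 members of each list with the highest means. A few of these genes and 2 of the pairs are not reported here, though they stay in all fits and list totals. Other genes named in the text were chosen after their values were seen. Because the tissue came from people, 221 entries were left out of naming, of gene lists and of the search for variable genes. They were sex-linked markers, genes with common deletions or strong effects of genotype, and immune receptor and histocompatibility genes.

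For each pair, log2((a + 1)/(b + 1)) was computed within each library, so that the scaling between libraries had almost no effect. Its mean over the 5 libraries was tested against 0 with limma version 3.58.1 (two-sided), with Benjamini-Hochberg adjustment over the 24 pairs and a threshold of 0.05. The moderated spread was estimated together with 2000 random pairs of measured genes that supplied only the spread. An exact sign-flip permutation test was run beside it, and with 5 libraries its smallest two-sided p is 0.0625. As an alternative, edgeR's quasi-likelihood test (version 4.0.16) was run on the recovered reads. Log2 ratios with a pseudocount of 1 understate differences of genes near 0. On simulated data for the gene pairs, with 2200 pairs in the fit, 100% of pairs with a log2 ratio of 2 or -2 were called. At a log2 ratio of -1 and 1 the shares were 74% and 58%, and 0.5% of 2000 pairs without a difference were called. The simulated genes had a common dispersion and the adjustment ran over all 2200 pairs. The real pairs had SDs from 0.12 to 2.37 and were adjusted over 24, so these shares need not hold for them.

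Gene list levels were medians of the members' percentile ranks within each library among measured genes, given as mean ± SD over libraries. Gene list spread was the median of the members' SDs of log2(value + 1), set against 10000 random lists of the same size matched on mean level in 20 bins. Lists with at least 5 measured members were called more variable at or above percentile 97 and less variable at or below percentile 3. This describes these libraries and gives no p-value. On simulated data for the list spread, with 25148 genes, all 3 lists given extra spread were called and 0 of the other 28 lists were. The simulated genes varied independently with a common dispersion, and the extra spread was large. The simulation therefore does not cover false calls among genes that move together, or lists with a small excess of spread. The deviation of a list in a library was the mean log2(value + 1) of its members minus that mean over the 5 libraries. For each reported gene and pair and each list, the gap between the most extreme library and its nearest neighbour, divided by the range, was compared with Dixon's 95% limit for 5 values. Values of single genes were compared between a library and the mean of the other libraries on the log2(value + 1) scale.

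Levels between genes were not corrected for length. The supplied annotation, GENCODE release 29 for GRCh38, differs in build from the deposited data and served only for gene lengths (89.0% of measured genes matched) and GC content (91.6% matched) in alternatives. Other alternatives were pseudocounts of 0.5 and 5, other minimum means, another scaling (the trimmed mean of M values, TMM, or total sums), 10 bins of mean level, and leaving out each library in turn. Computation used Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6, R 4.3.3 and matplotlib 3.10.9.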

Results

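Transcript levels were measured in 5 RNA-seq libraries from non-disease human right ventricle, all of 1 group. The libraries held 88055028, 85315932, 86906479, 87766496 and 80836646 assigned reads, in the order of library 1 to library 5. A mean normalized read count of at least 10 was reached by 17400 genes, and 23467 genes had a value above 0 in at least 1 library. The labels gave no second condition, so the comparisons set genes against each other within libraries and libraries against each other within the group. The 9 transcripts encoded by the mitochondrial genome that were sought were not analysed here.

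Contractile genes took a large share of the summed values, which held none of the 9 mitochondrially encoded symbols sought. TTN, which encodes the giant sarcomere spring titin, took 11.8% ± 2.36 (SD, n = 5) of the summed values, and MYH7, the slow ventricular myosin heavy chain, took 3.53% ± 0.478. The sarcomere list as a whole (24 of 24 members measured) took 20.9% ± 2.22. The 10 most abundant genes together took 21.9% ± 2.12, between 19.4% in library 5 and 24.2% in library 2. After TTN and MYH7 came RMRP at 1.52% ± 0.355 and RPPH1 at 1.15% ± 0.314, the RNA components of the ribonucleases MRP and P. DES, the muscle intermediate filament, stood at 0.885% ± 0.131 and RYR2, the calcium release channel, at 0.811% ± 0.105. MB, which encodes myoglobin, took 0.717% ± 0.159, and TPM1, MALAT1 and CMYA5 took 0.505%, 0.495% and 0.483%. These shares follow transcript length as well as abundance, and the long TTN transcript yields many reads per molecule.

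**Figure D1:**
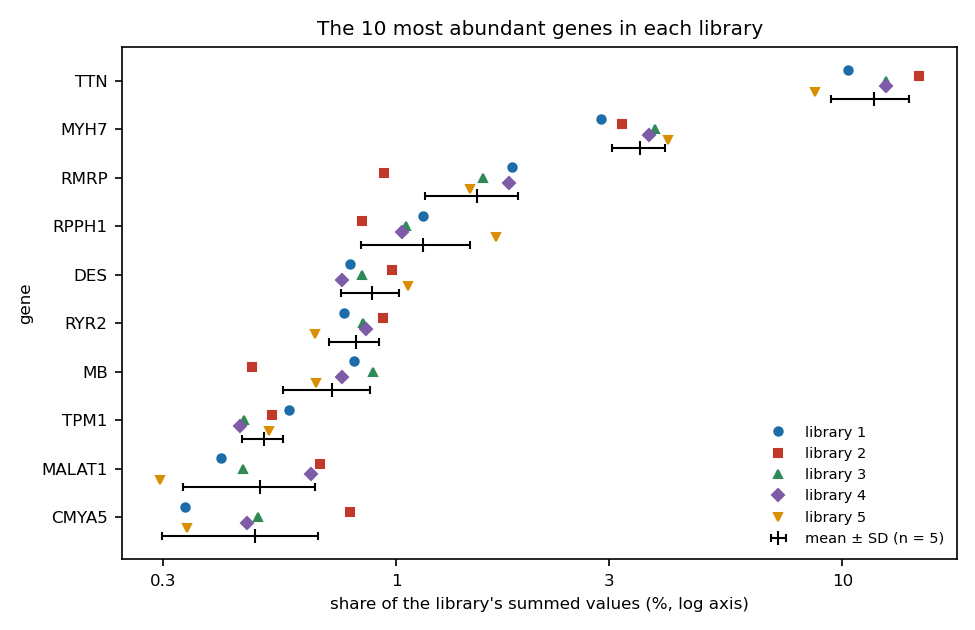
Share of each library's summed values taken by the 10 most abundant genes (horizontal log axis, percent), with 1 symbol per library and black bars for the mean ± SD of 5 libraries. TTN lies between 8.70% and 14.9% and is above every other gene in each library, whereas MALAT1 ranges from 0.296% to 0.676%.

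Muscle and energy genes ranked near the top of the measured genes. The median member of the sarcomere list stood at percentile 99.85 ± 0.0165 (SD, n = 5), that of the nuclear-encoded oxidative phosphorylation list at 99.17 ± 0.14, and that of the calcium handling list at 98.41 ± 0.101. Ribosomal proteins (98.23 ± 0.36), glycolysis and glucose use (98.12 ± 0.27) and fatty acid use (96.47 ± 1.16) followed. Natriuretic peptides and wall-stress genes stood at 98.9 ± 0.85, extracellular matrix at 93.57 ± 1.71, heat shock proteins at 90.54 ± 3.16, cardiac transcription factors at 86.19 ± 0.93 and hypoxia-responsive genes at 86.07 ± 1.74. The peptide genes NPPA and NPPB ranked lower than their list's median. By mean value they stood at percentile 79.1 and 77.5 of the listed genes, a wider set than the measured genes, and both peaked in library 2. Receptors and signalling of heart rate and load stood at 79.55 ± 1.63 and glucocorticoid-responsive and metallothionein genes at 76.08 ± 3.13. The circadian clock (70.68 ± 7.41), immediate early genes (65.07 ± 15.1), interferon-stimulated genes (63.32 ± 8.17) and ion channels and connexins (63.15 ± 7.08) lay in the middle. The cell cycle list (27.53 ± 1.89) and inflammatory and acute-phase genes (24.81 ± 10.4) were the lowest functional lists.

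Among cell type lists, ventricular cardiomyocyte markers ranked highest, at percentile 99.86 ± 0.04, against 60.03 ± 11.3 for atrial cardiomyocyte markers. Fibroblast (92.82 ± 2.32), pericyte (92.46 ± 1.75), smooth muscle (91.07 ± 3.12) and endothelial markers (89 ± 1.19) came next. Markers of macrophages and monocytes stood at 71.96 ± 10.4, conduction cells at 57.15 ± 9.02, Schwann cells and neurons at 56.54 ± 8.3, endocardium at 56.25 ± 3.56, lymphatic endothelium at 55.76 ± 6.82 and adipocytes at 52.26 ± 19. Skeletal muscle (28.35 ± 4.3), mast cell (26.45 ± 5.38), T and NK cell (14.84 ± 4.09), neutrophil (14.53 ± 14.8) and epicardial and mesothelial markers (10.04 ± 3.32) ranked lowest. Ranked among all genes above 0 in any library, these lists stood at 36.2, 45.4, 36.8, 32.4 and 31.6 in the same order, with the cell cycle at 46.2 and inflammatory and acute-phase genes at 42.9. In all, 18 of 36 lists reached percentile 75 or more, and 17 did after values were divided by gene length, when hypoxia-responsive genes fell to 63.3 and receptors and signalling of heart rate and load to 72.9, and macrophage and monocyte markers rose to 81.6. The lists of B and plasma cells, erythroid cells, and globin and blood plasma transcripts had fewer than 5 measured members. Among those members, IGJ (405.7 ± 210.5), HBB (2380 ± 4630, with 10658 in library 2) and APOA1 (2058 ± 1418) had the highest mean values ± SD.

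Ventricular forms exceeded their atrial counterparts within every library, and the other pairs of cardiac genes given here also kept their direction. MYH7 exceeded MYH6, the fast atrial myosin heavy chain, by a log2 ratio of 4.52 ± 1.29 (SD, n = 5; 23-fold; limma adjusted p = 8.98e-05). The ventricular light chains MYL2 and MYL3 exceeded the atrial MYL7 and MYL4 by 3.54 ± 1.08 and 3.49 ± 1.09. TNNI3, the adult cardiac troponin I, exceeded the slow skeletal form TNNI1 by 6.43 ± 2.37, with TNNI1 at 410.8 in library 1 and 417.8 in library 5 against 3930 to 6676 in the others. PLN, the phospholamban gene, exceeded its atrial relative SLN by 11.88 ± 1.28 (adjusted p = 1.62e-06). The ventricular factor IRX4 exceeded the atrial factor NR2F1 by 3.33 ± 0.88, HAND2 exceeded HAND1 by 3.05 ± 0.36, and TBX20 exceeded TBX5 by 1.62 ± 0.44. Connexin 43 (GJA1) exceeded connexin 40 (GJA5) by 3.67 ± 0.86, and the inward rectifier KCNJ2 exceeded the atrial KCNJ3 by 6.43 ± 1.84.

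Genes of energy metabolism showed the muscle or heart form above the widespread form in most pairs. COX6A2 exceeded COX6A1, both subunits of cytochrome oxidase, by 2.39 ± 0.12, the smallest spread of all pairs (limma adjusted p = 4.79e-06). COX7A1 exceeded COX7A2 by 1.51 ± 0.32, the muscle creatine kinase CKM exceeded CKB by 4.58 ± 0.42, and the muscle enolase ENO3 exceeded ENO1 by 1.78 ± 0.25. LDHB, the heart lactate dehydrogenase, exceeded LDHA by 3.56 ± 0.53, and the insulin-responsive glucose transporter SLC2A4 exceeded SLC2A1 by 2.28 ± 0.38. PPARA, a regulator of fatty acid oxidation, exceeded PPARG by 3.8 ± 0.53. PKM exceeded the liver form PKLR by 14.43 ± 0.85, with PKLR at a mean of 1.0 and a value of 0 in libraries 3 and 5, so the pseudocount sets the size of this ratio. The carnitine transferases ran the other way, since CPT1B, the muscle form, lay below CPT1A by a log2 ratio of -1.15 ± 0.24 (adjusted p = 0.000188), though not after values were divided by gene length (-0.19, adjusted p = 0.228). Among the remaining pairs, MMP2, a gelatinase, exceeded MMP9 by 8.79 ± 2.21, and COL1A1 lay below COL3A1, the type III collagen gene, by -2.93 ± 0.68.

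The natriuretic peptide genes differed in direction between libraries. NPPA exceeded NPPB by 1.99 ± 1.34 (limma adjusted p = 0.00646), in 4 of 5 libraries, and in library 2 the ratio was -0.18. All 24 pairs passed the threshold, with limma adjusted p between 1.08e-07 for PKM/PKLR and 0.00646 for NPPA/NPPB among the 22 reported here, and every pair except NPPA/NPPB had 1 direction in 5 of 5 libraries. A pass means only that the read counts of 2 genes differ, before any correction for length. This may hold for many pairs of genes, and the share of random pairs that would pass was not counted. edgeR's quasi-likelihood test on the recovered reads, where 100% of values were whole, also called 24. After values were divided by gene length, 22 of the 24 passed the threshold. Of the 22 reported pairs, 11 moved by more than 0.5 log2 units, with PPARA/PPARG at 2.26, TNNI3/TNNI1 at 9.42 and TBX20/TBX5 at 2.84, and the adjusted p of CPT1B/CPT1A ranged from 7.99e-05 to 0.228 over its 10 alternatives. The exact sign-flip permutation test cannot go below p = 0.0625 with 5 libraries and so called 0. MYH6 and MYH7 share long near-identical stretches, so their reads can be assigned to the wrong member.

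**Figure D2:**
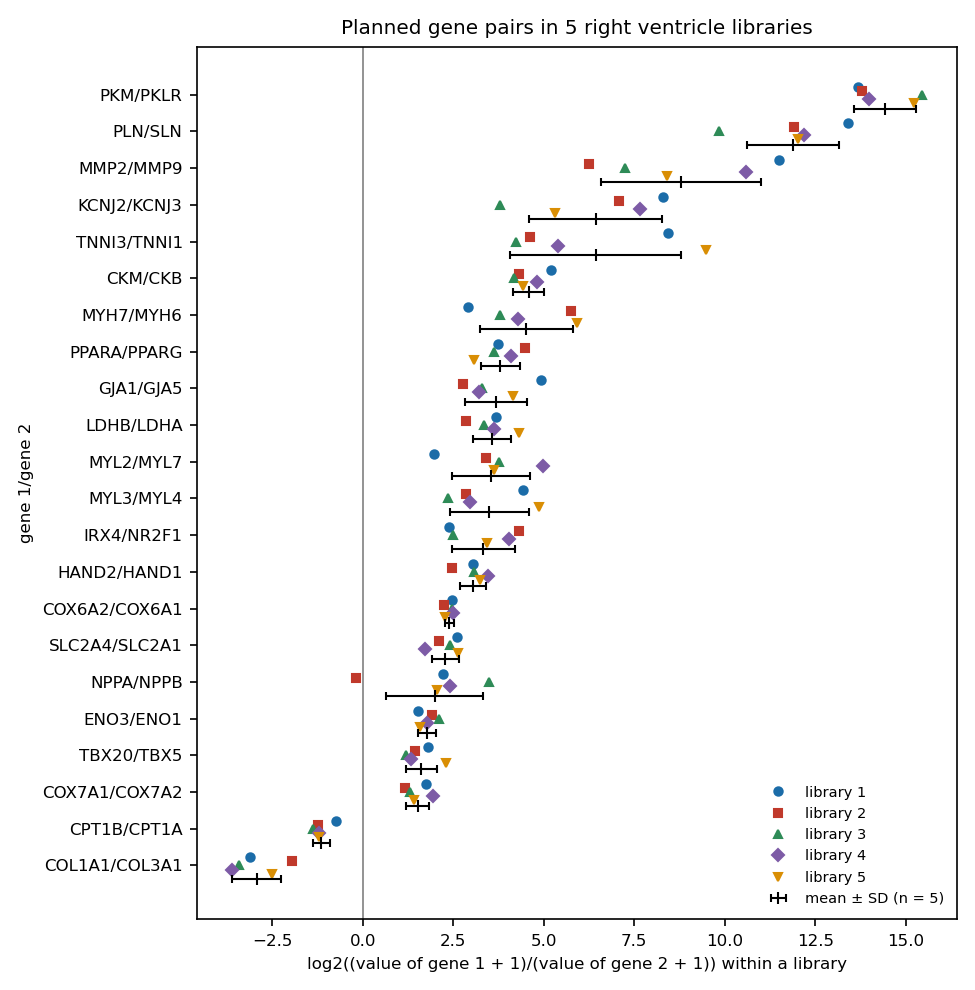
Log2 ratio of the members of each of 22 of the planned pairs within each library (1 symbol per library), with black bars for the mean ± SD of 5 libraries and a line at equal values. PKM/PKLR has the highest ratios, whose size depends on the pseudocount because PKLR is near 0, and CPT1B/CPT1A and COL1A1/COL3A1 lie below 0 in every library.

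Some genes differed widely between libraries. NPPB, the B-type natriuretic peptide, stood at 8441 in library 2 and between 14.1 and 239.2 in the others. COMP, a cartilage matrix protein, reached 1999 in library 2 and at most 5.93 elsewhere, and AQP4, a water channel, stood at 5.73 in library 2 against 351.7 to 1335 elsewhere. CYP1A1, an enzyme induced through the aryl hydrocarbon receptor, stood at 4145 in library 2, 2394 in library 4 and 1530 in library 1, but at 70.4 and 58.3 in libraries 3 and 5. UGT2B4, a glucuronidation enzyme, stood at 7.41 in library 3 and between 1016 and 4563 elsewhere. FABP2 stood at 476.7 and 350.4 in libraries 1 and 3 and at no more than 16.6 in the others, GLT1D1 ranged from 0 to 437.6, and SSTR5, a somatostatin receptor, from 11.5 to 1926. ZFP57 stood at 3.69 in library 5 and between 178.1 and 520.2 elsewhere.

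Of 13489 genes with a mean of at least 100, 361 (2.68%) had an SD above 1 on the log2 scale, and the median SD was 0.226. Without library 2 the number was 200, of which 166 were among the 361. With a minimum mean of 10 it was 1163 and with a minimum of 1000 it was 92, counted over different numbers of genes.

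**Figure D3:**
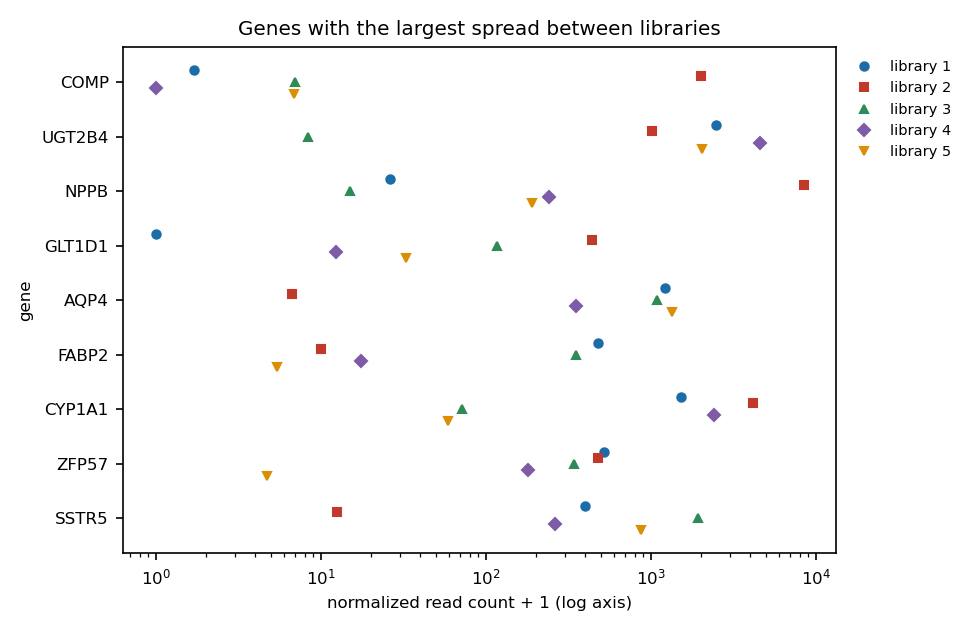
Normalized read count plus 1 (horizontal log axis) of 9 of the 10 genes with the largest SD of log2(value + 1), with 1 symbol per library. NPPB and COMP peak in library 2 at 8441 and 1999, and UGT2B4 ranges from 7.41 in library 3 to 4563 in library 4.

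Most gene lists were more variable between libraries than random lists of equal expression. Immediate early genes, which respond within minutes to stimulation, had a median SD of 1.05 against 0.22 for random lists, and 11 of 20 members had an SD above 1. Natriuretic peptides and wall-stress genes had a median SD of 0.96 against 0.20, inflammatory and acute-phase genes 1.29 against 0.37 (11 of 14 members above 1), and the circadian clock 0.64 against 0.20. Neutrophil markers had the highest median SD, 2.45 against 0.48, with 6 of 6 members above 1. Adipocyte markers (1.24), atrial cardiomyocyte markers (1.13, 6 of 8 above 1), endocardial markers (1.06), T and NK cell markers (1.02) and Schwann cell and neuron markers (1.01) also had medians above 1. Calcium handling genes had a median SD of 0.18 against 0.23, at percentile 8.01 of the random lists, but at 62.38 without library 2. Nuclear-encoded oxidative phosphorylation (percentile 36.29), ribosomal proteins (34.63), glycolysis and glucose use (55.31) and the cell cycle (28.06) lay inside the range of random lists. None of these lists was called under any alternative, though their percentiles moved between 5.96 for the cell cycle and 94.07 for ribosomal proteins, both under total-sum scaling.

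In all, 26 of 36 lists were called more variable and 0 were called less variable. Some lists share members, so these calls are not independent. MYH7, for example, is in the sarcomere and ventricular cardiomyocyte lists, and NPPA in the wall-stress and atrial cardiomyocyte lists. The others called were the sarcomere, ion channels and connexins, cardiac transcription factors, extracellular matrix, heat shock proteins, interferon-stimulated genes, hypoxia-responsive genes, glucocorticoid-responsive and metallothionein genes, and receptors and signalling of heart rate and load. The further cell type lists called were ventricular cardiomyocyte, fibroblast, lymphatic endothelial, smooth muscle, pericyte, macrophage and monocyte, and mast cell. Fatty acid use (percentile 94.73), conduction cell (94.61), skeletal muscle (96.01), endothelial (90.92) and epicardial and mesothelial markers (82.66) were not called. Without library 2, 22 lists were called, and heat shock proteins (percentile 94.41), hypoxia-responsive genes (80.1) and mast cell markers (34.12) dropped out, while the neutrophil list was then too short to be tested. The sarcomere call was lost without library 1, 3 or 5, at percentile 95.09, 96.6 and 79.91, and so was that of T and NK cells, at 94.19, 94.95 and 95.47. Ventricular cardiomyocyte and pericyte markers fell below the threshold without library 4 (96.3 and 95.49) or library 5 (96.33 and 81.84), heat shock proteins also without library 1 (88.05) or 5 (96.64), and hypoxia-responsive genes also without library 3 (96.34). Fatty acid use was called without library 1, 3 or 5 (98.05, 97.52 and 98.73), skeletal muscle markers without library 4 (97.36) and endothelial markers without library 5 (97.79).

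Library 2 had the highest levels of the wall-stress and matrix lists. The deviation of natriuretic peptides and wall-stress genes was 2.02 in library 2 (log2, from the mean of 5 libraries) and between -1.23 and 0.09 in the others, with a gap ratio of 0.592 within Dixon's limit, and 8 of 9 members were higher there by more than 1 log2 unit than the mean of the other libraries. NPPA, the atrial natriuretic peptide, reached 7447 in library 2 against 120.6 to 1264, and ANKRD1, a stretch-responsive titin partner, 405410 against 96001 to 203640. The extracellular matrix list deviated by 0.85 in library 2, with 9 of 24 members higher by more than 1, and FN1 (fibronectin) at 76768 against 18455 to 32755. Neutrophil (3.07), inflammatory and acute-phase (1.47), endocardial (1.29), immediate early (0.98), smooth muscle (0.71), heat shock (0.54) and hypoxia-responsive lists (0.53) were also highest in library 2. PDK4, which restrains pyruvate oxidation, stood at 225480 in library 2, and NR4A3, an immediate early gene, at 22344 against at most 3797 in the others. HBB, the beta-globin gene, reached 10658 in library 2 and 91.1 to 474.1 elsewhere.

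Other lists were lowest in library 2. Adipocyte markers deviated by -1.32, mast cell markers by -1.24, Schwann cell and neuron markers by -1.07, lymphatic endothelial markers by -1.05, and macrophage and monocyte markers by -0.97. TPSAB1, a mast cell tryptase, stood at 34.4 in library 2 and at 159.3 to 201.5 elsewhere, and LYVE1, a lymphatic and macrophage marker, at 894 against 2505 to 4297. KCNIP2, a subunit of the transient outward potassium channel, stood at 207 in library 2 and between 7787 and 9110.5 in the others. Ventricular cardiomyocyte markers deviated by -0.21 and endothelial markers by -0.04. Of 13489 genes, 115 were higher and 115 lower in library 2 by more than 2 log2 units than the mean of the other libraries, against 27 and 37 in library 1, 18 and 13 in library 3, 14 and 19 in library 4, and 35 and 39 in library 5.

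Library 5 had the highest level of the adipocyte list and the lowest of the immediate early list, though the gap ratios of both, 0.427 and 0.456, lay within Dixon's limit. Adipocyte markers deviated by 1.56 in library 5, with PLIN1, which coats fat droplets, at 4410.5 against 294.4 to 974.4 elsewhere, and FABP4 at 5266 against 1052 to 3447. Macrophage and monocyte markers (0.83) and Schwann cell and neuron markers (0.89) were also highest there. Immediate early genes deviated by -1.36, and 11 of 20 members were lower than the mean of the other libraries by more than 1 log2 unit. DUSP1, a phosphatase of stress kinases, stood at 2805 against 14530 to 28130, and NR4A3 at 146.2 against at least 1623 elsewhere. PDK4 stood at 1976 in library 5 and at 19136 or more in the others.

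Fewer genes stood apart in libraries 1, 3 and 4, though some lists deviated widely. Neutrophil markers deviated by -1.83 in library 1 and by -1.42 in library 4, and natriuretic peptides and wall-stress genes by -1.23 in library 1. T and NK cell markers deviated by 0.82 in library 1 and by -0.92 in library 3, and fibroblast markers by 0.45 in library 1. Atrial cardiomyocyte markers were highest in library 3 (0.60), where MYL4 stood at 38392 against 6542 to 25687 and KCNJ3 at 423.7 against 25.9 to 139.5. Of the 8 measured atrial markers 6 were higher there than the mean of the other libraries, whereas NPPA and MYL7 differed from that mean by -2.53 and -0.66 log2 units. In library 4, interferon-stimulated genes deviated by -0.45 and smooth muscle markers by -0.50, and FHL2, a muscle adaptor protein, stood at 191810 against 51782 to 69951. The strand setting of the counting was not given, so reads of genes with an antisense partner, such as NPPA and KCNIP2, cannot be told from those of the partner.

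**Figure D4:**
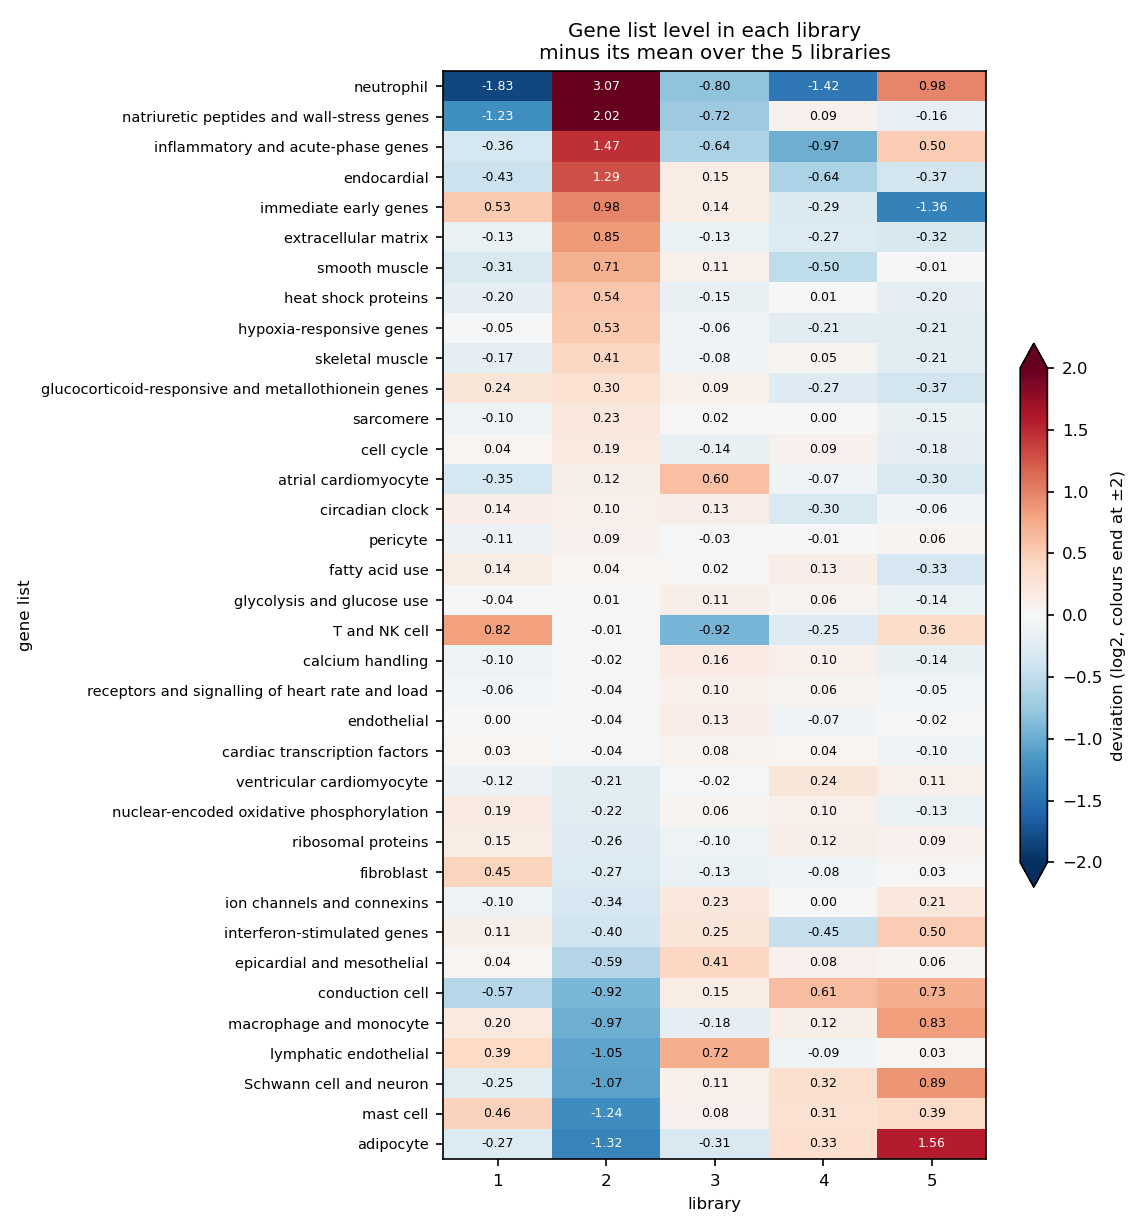
Deviation of 36 gene lists in each library from the mean of the 5 libraries (log2 scale, printed in each cell, red above and blue below the mean), sorted by library 2. The neutrophil list spans from -1.83 in library 1 to 3.07 in library 2, and the adipocyte list from -1.32 in library 2 to 1.56 in library 5.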

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

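The test of atrial muscle in library 2 and the test of histone genes were chosen after the results were seen. A library was singled out where its gap to the nearest other library, divided by the range of all 5, exceeded Dixon's 95% limit for 5 values. This held for 27 of 250 results, and library 2 was the library concerned in 15 of them. A 95% limit alone would flag 12.5 of 250 results by chance. The results include genes chosen for a large SD and lists together with their own members. They are therefore not independent, and this chance count does not allow for the selection.

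In library 2, KCNIP2 was low with a gap ratio of 0.958 (a log2 difference of -5.36 from the mean of the other libraries) and EGLN3, an oxygen-sensing hydroxylase, was high with 0.942 (difference 1.94). The extracellular matrix list was high with 0.837, the hypoxia-responsive list with 0.776 and the heat shock list with 0.717, and the mast cell list was low with 0.78. With medians over members in place of means, only the hypoxia-responsive (0.827) and mast cell lists (0.841) stayed past the limit. The hypoxia-responsive list lay within the limit under total-sum scaling (0.598), and the heat shock list after the trend on length and GC content was removed (0.616). Mast cell genes TPSAB1 (0.866) and MS4A2 (0.736), the fibroblast receptor PDGFRA (0.736), the water channel AQP4 (0.748) and MYL3 (0.737) were low there. COMP (0.745), the lipase LPL (0.759), VEGFA (0.741) and MYL2 (0.711) were high there.

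In library 5, the fatty acid use list was low with a gap ratio of 0.741, but its members as a group lay inside the range of random lists. Their median difference from the other libraries was -0.16, at percentile 27.69 of random lists. Of 19 members, 5 were higher by any amount and 0 by more than 1 log2 unit. Only 1 member, PDK4, was lower by more than 1, with a difference of -4.85. DUSP1 was low with 0.713, ZFP57 was low with 0.773 and the pericyte receptor PDGFRB was high with 0.764. In library 1, the CPT1B/CPT1A ratio was high with 0.713, MYH7 was low with 0.716 and VWF, the von Willebrand factor gene, was low with 0.829. In library 3, UGT2B4 was low with 0.762, the B cell gene MS4A1 was low with 0.802 at values of at most 18.2, and KRT19 was high with 0.725. In library 4, FHL2 was high with 0.77 and PLVAP was low with 0.768.

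The pattern of library 2 covered 230 genes more than 2 log2 units from the mean of the other libraries. A smooth trend on gene length and GC content was fitted to genes within 2 log2 units of their mean in every library. It took up 3.8% of the variance of their deviations in library 2. The median difference in each gene's own direction, up or down, was compared before and after its removal. Over the 222 pattern genes with a known length and GC content, this was 2.37 before and 2.39 after the trend was removed. The pattern genes were chosen for a large difference, so removal of so weak a trend could hardly lower their median. The comparison therefore cannot decide whether length or GC bias caused the pattern. It shows only that the fitted trend was weak and left these differences in place. A bias that acts only on genes outside that fit was not tested. Atrial muscle in the sample would raise atrial markers together, but their median difference without NPPA was -0.64, with 2 of 7 higher. A lower share of muscle cells would raise the other cell types alike, but the medians of 13 non-muscle lists spanned 5.91 log2 units, from -1.96 for mast cells to 3.95 for neutrophils, and 9 lay below 0. A difference in the tissue or its handling may remain as a candidate explanation, and because the labels give 1 group no biological explanation beyond the mix of cell types was tested.

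For the lipid genes named as high in library 5, adipose tissue in the sample is a candidate explanation, since the 8 adipocyte markers had a median difference of 1.39 and 7 of 8 were highest in library 5, with ADIPOQ higher by 3.59, CIDEC by 3.99, FABP4 by 1.14 and PLIN4 by 0.48. All 8 markers had values above 0 in the other libraries too, and LEP was highest in library 4. SCD at 58997 lay far above ADIPOQ at 4204 and PLIN1 at 4410.5 in library 5, and whether adipose tissue could account for its level was not tested. The same trend on length and GC content took up 11.8% of the fitted genes' variance in library 5, the largest share. SCD was higher in library 5 by 5.39 log2 units before and 5.41 after removal of the trend. FASN was higher by 3.78 and 3.43, and ADIPOQ by 3.59 and 3.66. PLIN4 fell from 0.48 to 0.18 and LIPE from 0.81 to 0.53. Over 70 of the 74 genes, high or low, that lay beyond 2 log2 units in library 5, the median difference in each gene's own direction was 2.72 before and 2.82 after. SCD, FASN and these 74 genes were chosen for large differences, and the fit left out genes far from their mean. The removal therefore shows only what the fitted trend accounts for, and cannot decide on length or GC bias as a cause. No biological explanation beyond the mix of cell types was tested.

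RMRP and RPPH1, small RNAs without a poly(A) tail, were among the 10 most abundant genes. RNA without a tail may have been kept in the libraries, and histone genes, most of whose transcripts lack a tail, were examined for this. Their median percentile among all listed genes was 46.6 over 69 genes, between the bounds set for either answer, so this cannot be told apart from a low yield of such RNA. Histone levels also depend on cell division, and the cell cycle list stood at 49.2 on the same scale, so this test cannot decide. SCARNA2, another RNA without a tail, stood at a mean of 73278.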

How the results depend on the processing

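The alternatives that removed a trend on length and GC content, rescaled the list deviations by TMM or total sums, or took medians over members were chosen after seeing the data. All 24 pairs kept their direction and their call under both other pseudocounts, each left-out library and edgeR; the exact permutation test called 0 pairs because 5 libraries cannot reach its threshold. The number of genes with an SD above 1 was 1163 at a minimum mean of 10 and 92 at a minimum of 1000, where the number of genes tested differs, and 200 to 438 when each library was left out, with 200 without library 2. It was 325 to 367 under the other scalings and pseudocounts and after the trend was removed. The number of lists called more variable was 22 to 27 under every alternative. TMM rescaling, total-sum scaling and removal of the trend each added fatty acid use; total-sum scaling removed heat shock proteins (percentile 94.64) and removal of the trend removed pericytes (88.48). Total-sum scaling shifted the median gene by -0.12 in library 2 and 0.11 in library 5 (log2), and changed the sign of 15 of 180 list deviations, none larger than 0.1; TMM changed 6, none larger than 0.02. With medians over members in place of means, 2 lists rather than 5 had a library out of line, since extracellular matrix, heat shock and fatty acid use were lost. Removal of the trend left 4, without heat shock, and total-sum scaling gave 4, with pericytes gained and fatty acid use and hypoxia-responsive genes lost. The share of the 10 most abundant genes was 21.3% to 22.5% with each library left out, and 17303 to 17435 genes were then measured. Without the filter on low values 20 lists reached percentile 75, and 24 of 36 list levels moved by more than 1 SD; after division by length 18 did. The share without mitochondrially encoded genes was not run because no such gene was among those used here. No paired analysis was possible because the labels give 1 group only. Depth was similar in all libraries, from 80836646 to 88055028 reads, and limits mainly genes such as PKLR with a mean of 1.0.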

Other observations

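Of the 13 circadian clock genes, ARNTL, PER2 and PER3 were picked after their values were seen, and the other members were not tallied. ARNTL, an activator of the clock, stood at 1261 and 1116 in libraries 4 and 5 and at 304.2, 498.1 and 165.2 in libraries 1, 2 and 3. Its opponents PER2 and PER3 stood at 797 and 1785 in library 4 and at 792.8 and 1997 in library 5, and at no less than 2110 and 3333 in the other libraries. PER1 followed them, at 2883 and 1994 in libraries 4 and 5 against 3422 to 5890 elsewhere. CLOCK was highest (7868) and NR1D2 lowest (3936) in library 4, but neither stood apart in library 5 (5760 and 6240).

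Among genes outside the fixed lists, 5 genes of lipid synthesis were picked because they were highest in library 5, and other genes of that pathway were not examined as a group. SCD, a fatty acid desaturase, stood at 58997 against at most 3107, and FASN, the fatty acid synthase, at 23223 against at most 2286. SREBF1, which encodes a regulator of lipid synthesis, stood at 7263 against at most 2154, and its known targets INSIG1 and FADS2 at 4776 and 5690.5 against at most 1699 and 1867.

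THBS1 and CTGF, outside the named set, were picked after their values were seen and were highest in library 2. THBS1, a thrombospondin, stood at 65265 against 3420 to 8583 elsewhere, and CTGF, a matrix-associated growth factor, at 14932 against at most 1425.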
